A study of Mus musculus with 4 samples.

How the data were processed

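RNA was prepared with a kit for total RNA including small RNA, amplified and labelled with Cy3 as complementary RNA, per the labels' protocols, and hybridised to 4 Agilent mouse arrays of design 014868 on 1 slide, 1 sample per array. The intensity values per spot were made, per the file headers, with Agilent Feature Extraction 10.5.1.1: outlier pixels were rejected, spatial trends and local background were removed, and dim spots received surrogate values, with no normalization between arrays. The authors' log2 values of the same arrays, as deposited, were found by comparison to be the log2 processed intensity plus 1 constant per array that sets the medians equal, at 5.026 on each array, with 99.9% of matched probes within 0.01 of the constant; how they were made is not stated. They served as an alternative.

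The values analysed here were computed from the processed intensity. Control spots and spots with an outlier flag were left out, log2 values of the spots of a probe were averaged, and each array's 75th percentile over 41174 probes was subtracted. The percentile stood at an intensity of 586 and 486 on the wild-type arrays and 514 and 493 on the knockout arrays. Levels are given on this scale, so that 0 is the 75th percentile of an array, and differences are knockout minus wild type. Probes were named through the accessions of the array annotation and a table of RefSeq genes of assembly GRCm38.p6, which was used for names and neighbouring genes only: 26888 probes matched by their systematic name, 95 by another RefSeq accession, and 14191 kept the name of the array files. Coordinates are those of the array files, build mm9.

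Each gene was represented by its probe with the highest mean over the 4 arrays, and other probes are given beside it for named genes where they differed most. Of 28500 genes, 16780 were tested, those whose probe was well above background on both arrays of at least 1 group. Genotypes were compared with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested genes at 0.05, and errors are limma's moderated standard errors with n = 2 arrays per group. Of these genes, 12173 carried a name matched through RefSeq.

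Before the data were examined, 26 gene lists of 540 entries were fixed, of which 480 were tested and 10 had no gene on the array: miR-223 targets named in earlier literature, azurophil granule, specific granule, and mature neutrophil and gelatinase granule genes, NADPH oxidase genes, myeloid transcription factors, DNA replication, mitosis, ribosomal protein, glycolysis and hypoxia, cholesterol synthesis, interferon response, inflammatory cytokine and NF-kB, immediate-early and heat shock, reference and sex-linked genes, X-chromosome neighbours of Mir223, and markers of macrophages and monocytes, dendritic cells and MHC class II, mast cells and basophils, eosinophils, B cells, T and NK cells, erythroid cells, megakaryocytes, and stem and progenitor cells. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists. Each was tested again with a correlation estimated from the arrays. With few residual degrees of freedom, this second test could hardly give a call. Fry, which does not compare a list with other genes, was run alongside. The percentile of each list's median among 10000 random lists of genes of matched mean signal was added after the data were seen. The genes of random lists were drawn singly, so that these lists ignore correlation among the genes of a list.

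Named genes followed a rule fixed before the data were examined: up to 12 genes per direction with the largest difference among those past the threshold, or, since none passed, with the smallest p among genes with a symbol and all knockout arrays on one side of the wild-type arrays; up to 4 members of each list with the smallest p; and any measured miR-223 target or sex-linked gene. With arrays simulated over 16780 genes at this size, limma called 0% of genes changed by 0.5 on the log2 scale, 4% at 1, 70% at 2 and 88% at 4, with 2 false calls. At each size 50 genes were changed, and the rates depend on how many genes change. Counts of miR-223 sites in 3' UTRs were planned and were not analysed here, because no 3' UTR sequences were used. The software was R 4.3.3 with limma 3.58.1, jsonlite 2.0.0 and the data.table package (1.17.8).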

Results

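The series measured gene expression in granulocytes of mice that lack miR-223, a microRNA of the myeloid lineage, and of wild-type mice. Bone marrow cells of male C57BL/6 mice were cultured for 4 days with 40 ng/ml GM-CSF, a cytokine that drives granulocyte and macrophage growth, and expanding immature granulocytes were sorted. Total RNA was labelled with Cy3 and hybridised to 4 Agilent whole-genome mouse arrays, 2 wild type and 2 miR-223 knockout. The comparison asks which transcripts differ in these cells when miR-223 is absent. On each array, 57.6% to 63.5% of 41174 probes were well above background, and no spot was saturated. The number of arrays limits the precision: the median standard error (SE) of a knockout minus wild-type log2 difference was 0.157. P-values of single genes measure only the spread between these samples. That spread may be technical, since the labels do not say that replicates came from separate animals. For lists, camera with the preset correlation takes genes as nearly independent units. Its p-values, the percentages of random lists and the ranks of sites in probe sequences thus measure spread over genes, and they too hold only for these samples.

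The arrays of both genotypes were close to each other over 16780 tested genes. Pearson correlations across genes, which are not independent replicates, were 0.990 between the wild-type arrays, 0.994 between the knockout arrays and 0.985 to 0.991 between genotypes. The value of 0.991 was that of wild-type array 1 with knockout array 1, above that between the wild-type arrays. Principal component 1 held 55.6% of the variance and placed the wild-type arrays at -14.2 and -40.4 and the knockout arrays at 24.8 and 29.8. Of the male-specific genes Ddx3y, Eif2s3y, Kdm5d and Uty, encoded on the Y chromosome, all 4 were measured in both genotypes (Uty well above background on 1 of the 2 wild-type arrays), with log2 differences of -0.19 for Ddx3y and 0.07 to 0.20 for the others, whose sign turned under some of the other settings. The probe chosen for Xist did not pass the filter on dim probes. As a list, the sex-linked genes had an adjusted p of 0.973 (camera), with a median of 0.07 although camera ranked the list as lower.

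The targeted gene could not be checked, because no probe was named for Mir223 and 0 probes lay between Msn and Vsig4, the nearest coding genes on either side of it on the X chromosome. Msn, which links actin to the cell membrane, had a log2 difference of 0.32 ± 0.13 (SE, n = 2 arrays per group; adjusted p = 0.39, limma), and Vsig4 was not well above background on any array. Among 9 measured X-chromosome neighbours of Mir223, the median log2 difference was 0.08 and 0 passed over all genes (limma camera adjusted p = 0.973, ranked as lower, opposite in sign to the median). Spin4 had a difference of -0.80 ± 0.22, Yipf6 one of 0.35 ± 0.12 (another probe 0.00) and Efnb1 one of -0.26 ± 0.14.

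Genes named as miR-223 targets in earlier literature rose as a list in the knockout, with 17 of 22 measured members higher and a median log2 difference of 0.17, which ran from 0.07 with spike-in scaling to 0.32 without miR-223 knockout replicate 1. Among the members that were higher, the largest differences were those of Lmo2, a transcriptional cofactor of blood progenitors, at 0.91 ± 0.13 (SE, n = 2 per group; 1.88-fold) and Igf1r, the receptor for insulin-like growth factor 1, at 0.82 ± 0.14. They were followed by Nfia, a transcription factor that counters granulocyte differentiation, at 0.77 ± 0.16, Cbx5, a heterochromatin protein, at 0.73 ± 0.18 (other probes 0.18 and 0.24), and Sp3, a transcription factor, at 0.72 ± 0.17 (other probes 0.38 and 0.64). The probes read Lmo2 on chromosome 2 (103816341 to 103821054, mm9) and Igf1r on chromosome 7 (75376998 to 75377057), and 3 other probes of Igf1r gave 0.72 to 0.77. Smaller positive values were found for Hmgcs1 (0.64, with other probes from -0.31 to 0.71), Pknox1 (0.43), Stat3 (0.40), Stmn1 (0.32) and Mef2c (0.19), and the cell cycle regulator E2f1 was at 0.10 ± 0.15, with a sign that turned under some settings. Il6st, the signalling chain of the interleukin-6 receptor, was at -0.80 ± 0.14 and the chemokine gene Cxcl2 at -1.88 ± 1.0, with its wild-type arrays at 1.90 and 4.08. The remaining higher members were Fbxw7 (0.35, another probe 0.05), Nlrp3 (0.15), Lpin2 (0.15, other probes -0.21 to 0.68), Parp1 (0.09), Chuk (0.07, another probe -0.09) and Scarb1 (0.01). The remaining lower members were Foxo1 (-0.22, another probe 0.07), Rhob (-0.16) and Msmo1 (-0.10). Their values under other settings are not given. Adjusted over the list alone, 5 members passed as higher (Lmo2, Igf1r, Nfia, Sp3, Cbx5) and 1 as lower (Il6st), and 0 passed over all 16780 genes (limma). The list's limma camera adjusted p was 0.0229 with a preset correlation of 0.01 and adjusted p = 0.85 with an estimated correlation, and fry gave an adjusted p of 0.099. The call was also lost without wild type replicate 1 (adjusted p 0.0538), without miR-223 knockout replicate 2 (0.122) and with the replicate number as a block (0.0611).

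**Figure D1:**
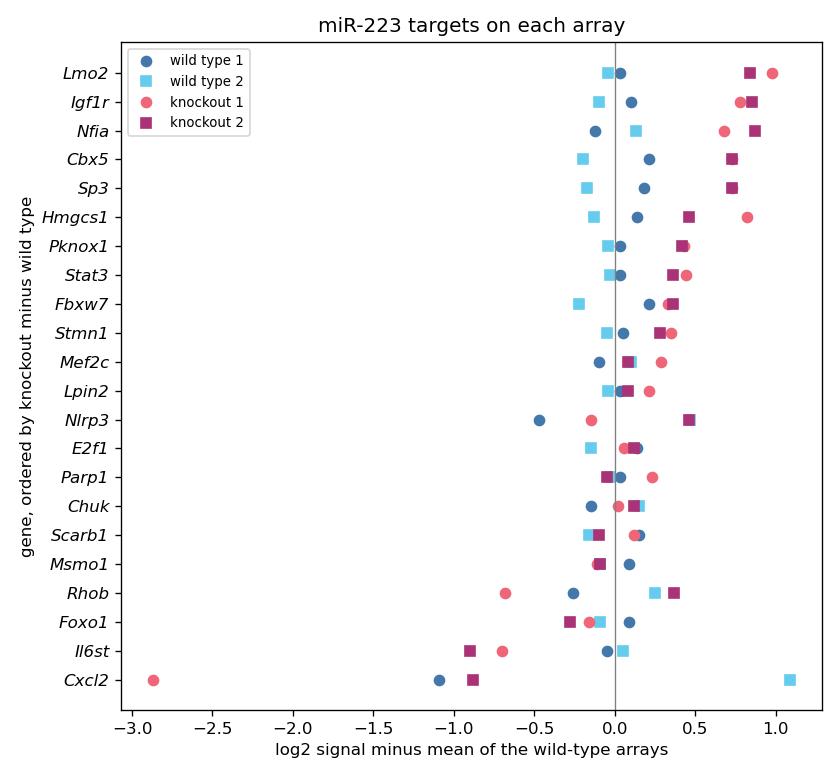
Each of the 22 measured miR-223 targets on each of the 4 arrays, as log2 signal minus the mean of the wild-type arrays, ordered by the knockout minus wild-type difference. Lmo2, Igf1r, Nfia, Cbx5 and Sp3 lie 0.72 to 0.91 above 0 on average, Il6st lies at -0.80, and other probes of Cbx5, not drawn, gave 0.18 and 0.24.

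Over all genes, none of the differences passed after adjustment. The highest-ranked genes in the knockout direction included Serpina3f, a serine protease inhibitor gene, at a log2 difference of 2.07 ± 0.15 (SE, n = 2 per group; 4.19-fold; chromosome 12, 105458964 to 105459023, mm9), Mgam, the maltase-glucoamylase gene, at 1.41 ± 0.12 (chromosome 6, 40718887 to 40718946), the metallothionein gene Mt2 at 1.41 ± 0.16 and the integrin gene Itgb3 at 1.26 ± 0.14. A second probe gave 1.51 for Serpina3f and 1.46 for Mgam, but 0.39 for Itgb3. For the autophagy kinase gene Ulk2 (1.36) other probes gave 0.09 to 0.48. Fbxo8 (1.35, another probe 0.82), Stkld1 (1.39), Dmkn (1.34), Tmem106b (1.08, other probes 0.41 to 0.55) and Sall3 (1.06, well above background on 1 wild-type array) followed. Crispld1 and Tbx19 were not well above background in wild type, and were at least 1.09-fold and at least 1.21-fold higher in knockout.

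In the other direction, Orm1 and Orm2, which encode the acute-phase plasma protein orosomucoid, had log2 differences of -1.70 ± 0.12 and -1.66 ± 0.12. These are near-identical gene copies, so that their probes may not tell them apart. The probe of Orm1 lies on chromosome 4 (63006483 to 63007090, mm9). Ccdc85a was at -1.71 ± 0.13 and Prkcq, a protein kinase C gene, at -1.77 ± 0.15. A further 8 genes were dim in wild type and not well above background in knockout, so that only bounds could be given. Each bound took for each dim array the higher of its lowest well-above-background signal and the probe's own. Cst10 was at least 8.51-fold lower in knockout, Cfap206 at least 4.39-fold, Wfikkn2 at least 3.56-fold, Atp6v1c2 at least 3.51-fold, Btg4 at least 2.82-fold, Olfr157 at least 2.67-fold, Prss51 at least 2.41-fold and Has2 at least 2.28-fold. For Btg4, Cst10, Cfap206 and Olfr157 both knockout values lay at the floor of the signal (SD 0.14 to 0.15 in each), so that their spread was not that of the genes. The smallest adjusted p (limma) was 0.0592, that of Btg4 and Cst10, followed by 0.132 for Cfap206 and Olfr157 and 0.156 for Serpina3f, Has2, Orm1, Orm2, Prss51 and Ccdc85a.

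Of the 16780 genes, 0 passed an adjusted p of 0.05 in either direction (limma), 2 passed 0.1, and 2275 had an unadjusted p under 0.05 (1348 higher and 927 lower in knockout), where chance gives 839. Both knockout arrays lay above both wild-type arrays for 4692 genes and below for 3371, together 48.1%, where chance gives 33.3%. Of these, 214 and 324 also differed at least 2-fold. Genes vary together across the arrays, so these counts can depart from the chance values without an effect of genotype. Other settings called between 0 and 5 genes at an adjusted p of 0.05. With arrays simulated at this size, limma called 70% of genes changed by 2 on the log2 scale and 4% of those changed by 1. In that simulation 50 genes were changed at each size, and the rates depend on how many genes change. They need not hold for these arrays, where Serpina3f, at 2.07 ± 0.15, had an adjusted p of 0.156 (limma).

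None of the 3 granule and neutrophil lists passed the test, and Orm1 was the 1 member that passed over its list alone. For specific granule genes, products of the later granulocyte precursors, 15 of 20 were higher, with a median of 0.28 (limma camera adjusted p = 0.176). Cd177, a surface glycoprotein of neutrophils, was at 0.77 ± 0.18 and Hp, haptoglobin, at 0.64 ± 0.16, while Orm1 was at -1.70 ± 0.12 and Ptx3, a soluble pattern recognition protein, at -1.07 ± 0.26. As a check on single members, 1 passed adjusted over the list alone (Orm1) and 0 passed over all genes (limma). Among 30 mature neutrophil and gelatinase granule genes, the median was 0.20 (limma camera adjusted p = 0.51), from 0.00 without wild type replicate 1 to 0.41 without wild type replicate 2. Of random lists of equally bright genes, 0.08% had a median as high as the specific granule list and 0.06% as high as the mature neutrophil list. Random lists ignore the correlation among genes of a list. It was estimated at 0.243 and 0.791 for these lists, from few residual degrees of freedom. With the estimated correlation, the limma camera adjusted p was 0.85 and 0.982. That test could hardly give a call, so it cannot tell whether correlation accounts for the ranks among random lists. The protease inhibitor gene Slpi was at 1.05 ± 0.18 and the decoy interleukin-1 receptor gene Il1r2 at 0.95 ± 0.22, against -1.18 ± 0.26 for Cstdc5, a cystatin of a cluster of close copies; 0 passed over all genes and 0 adjusted over the list alone. Azurophil granule genes had a median of 0.09 over 15 members (limma camera adjusted p = 0.752), with Cd63 at 0.44 ± 0.15 and Mgst1 at 0.29 ± 0.12, and 0 members passed either way. Specific granule genes passed without wild type replicate 2 (adjusted p 0.0317), without miR-223 knockout replicate 1 (0.0319), without the filter on dim probes (0.0196) and with normexp background correction (0.00393). Mature neutrophil genes passed as higher without wild type replicate 2 (0.0107) or without miR-223 knockout replicate 1 (0.0319), and turned to lower without wild type replicate 1 (0.263) or without miR-223 knockout replicate 2 (0.504).

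NADPH oxidase genes, which encode the enzyme of the respiratory burst, rose as a list: all 8 were higher, with a median of 0.19, Ncf1 at 0.57 ± 0.15 and Cybb at 0.39 ± 0.20. Glycolysis and hypoxia genes also rose, with 18 of 23 higher and a median of 0.23, among them Bnip3 at 0.75 ± 0.13, Ndrg1 at 0.67 ± 0.12, and the glycolytic enzyme genes Aldoa and Pgam1 at 0.34 ± 0.12 each. Ribosomal protein genes rose by a median of 0.19, with 29 of 30 higher (Rps14 at 0.50 ± 0.16, Rps23 and Rpl11 at 0.36). Adjusted over the list alone, Bnip3 and Ndrg1 passed and 0 members of the NADPH oxidase and ribosomal lists did; 0 passed over all genes (limma). The limma camera adjusted p was 0.0454 for NADPH oxidase genes, 0.0169 for glycolysis and hypoxia genes and 0.00127 for ribosomal protein genes, and adjusted p = 0.85 for each with an estimated correlation. The lowest medians over the alternatives were 0.09 (NADPH oxidase, spike-in scaling), 0.06 (glycolysis, quantile normalization) and 0.04 (ribosomal, normexp and quantile normalization). Quantile normalization ended all 3 calls (adjusted p 0.242, 0.242 and 0.726). NADPH oxidase genes also lost their call with spike-in scaling (0.0784) and the replicate block (0.0505). Of random lists of equally bright genes, 15.8% had a median as high as the ribosomal list, 8.47% as high as the NADPH oxidase list and 0.09% as high as the glycolysis list. The median of such lists was itself 0.15 for ribosomal, 0.09 for NADPH oxidase and 0.07 for glycolysis genes, so equally bright genes rose too. Without wild type replicate 1 the NADPH oxidase (0.301) and ribosomal (0.143) calls were lost, without miR-223 knockout replicate 2 the NADPH oxidase (0.285) and glycolysis (0.123) calls, and without wild type replicate 2 the glycolysis call (0.121).

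Macrophage and monocyte markers fell as a list in the knockout arrays, with 20 of 23 lower and a median log2 difference of -0.76 (1.70-fold). Mertk, a receptor for the uptake of dead cells, was at -2.04 ± 0.21 (SE, n = 2 per group), the fibronectin gene Fn1 at -1.91 ± 0.27 (other probes -1.93 and -1.07), the mannose receptor gene Mrc1 at -1.17 ± 0.20 and the matrix proteoglycan gene Vcan at -0.95 ± 0.13 (another probe -0.49). Both knockout arrays lay below both wild-type arrays for 17 of the 23 genes and above them for 3, where chance puts 33.3% of genes apart in either direction and 48.1% of all tested genes lay apart on these arrays. Adjusted over the list alone, 7 members passed as lower (Mertk, Vcan, Fn1, Mrc1, and outside the naming rule Msr1, Cd163 and Ccr2), and 0 over all genes (limma). The bright markers Csf1r, the receptor for the macrophage growth factor, and Cd68 were at -0.17 ± 0.20 and -0.09 ± 0.24, and the complement gene C1qb was at -1.07 ± 0.45 (-0.44 without miR-223 knockout replicate 2). The 3 members that were higher were Ctsl (0.86 ± 0.26), Adgre1 (0.75 ± 0.24) and Ly6c1 (0.47 ± 0.13), named here, like Csf1r, Cd68 and C1qb, after their values were seen. The limma camera adjusted p was 9e-07, and adjusted p = 0.85 with an estimated correlation; fry gave 0.365.

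Mast cell and basophil markers fell furthest, with 9 of 10 lower, a median of -1.41 (2.65-fold) and a large gap between the knockout arrays, at medians of -0.56 and -2.18 against the wild-type mean. That rank rested on knockout array 2. On knockout array 1, immediate-early (-0.91), inflammatory (-0.65), macrophage (-0.61) and megakaryocyte lists (-0.6) had lower medians. Il6 was at -2.09 ± 0.48, the transcription factor gene Gata2 at -1.92 ± 0.62, the mast cell protease gene Cpa3 at -1.63 ± 0.63 and the cytokine gene Il4 at -1.46 ± 0.46. On the 2 knockout arrays Cpa3 was at 1.74 and -0.10, against 2.45 on each wild-type array. Gata2 was at -0.03 and -1.83 (wild type 0.99 and 0.98), Il4 at -3.61 and -4.93 (-2.72 and -2.9) and Il6 at -1.76 and -3.13 (-0.35 and -0.37). None of the members passed over all genes or adjusted over the list alone (limma; 3 had an unadjusted p under 0.05). The limma camera adjusted p was 0.000112, and adjusted p = 0.85 with an estimated correlation; fry gave 0.616.

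Dendritic cell and MHC class II markers fell, with 14 of 19 lower and a median of -0.34, among them the costimulatory gene Cd86 at -0.77 ± 0.14 (another probe -1.05), the cytokine receptor gene Flt3 1.99-fold below wild type (log2 SE 0.29) and Siglech at -1.75 ± 0.53 (well above background on 1 of the 2 knockout arrays), against 0.54 ± 0.18 for the chemokine gene Ccl22. The medians of the knockout arrays were -0.04 and -0.58. The limma camera adjusted p was 0.0169, and adjusted p = 0.85 with an estimated correlation, and 0 members passed over all genes or over the list alone (limma; 6 at an unadjusted p under 0.05). The call was lost without wild type replicate 1 (adjusted p 0.0631), without miR-223 knockout replicate 2 (0.285) and without the filter on dim probes (0.0984).

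**Figure D2:**
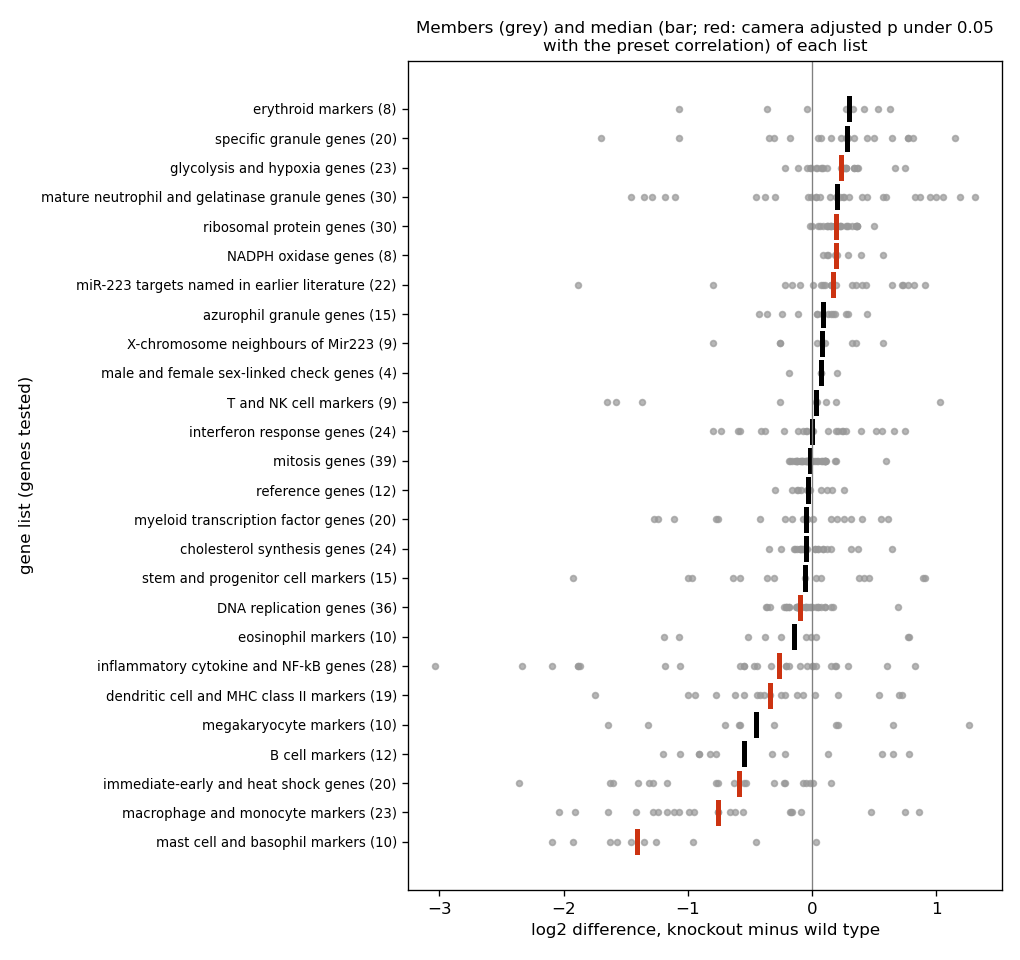
Log2 differences, knockout minus wild type, of the measured members of the 26 lists (grey points, 1 gene each) with each list's median as a bar, red where the limma camera adjusted p with the preset correlation was under 0.05. Medians run from -1.41 for mast cell and basophil markers to 0.30 for erythroid markers.

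Immediate-early and heat shock genes, which respond within minutes to stimuli and stress, fell as a list, with 18 of 20 lower and a median of -0.59, but the knockout arrays stood apart, at medians of -0.91 and -0.10 against the wild-type mean. Hspa1a and Hspa1b, inducible heat shock genes of almost the same sequence, were at -1.31 ± 0.47 and -1.17 ± 0.39, and the transcription factor genes Egr2 and Atf3 at -0.77 ± 0.21 and -1.63 ± 0.67. Without wild type replicate 2 the value of Atf3 was -0.66, and without miR-223 knockout replicate 1 those of Hspa1a and Hspa1b were -0.63 and -0.62. Inflammatory cytokine and NF-kB genes also fell, with 20 of 28 lower and a median of -0.27. The chemokine gene Cxcl1 was at -3.03 ± 0.63 (8.15-fold), Ptgs2, which encodes an inducible prostaglandin synthase, at -2.33 ± 0.53 (another probe -2.86), Il6 at -2.09 ± 0.48 and the chemokine gene Ccl4 at -1.18 ± 0.26. The knockout arrays' medians were -0.65 and -0.02, and the median gap between the wild-type arrays was -0.61, and without wild type replicate 2 the list's median was 0.03. Within replicate numbers 1 and 2, the medians were -0.74 and -0.29 for immediate-early genes and -0.34 and -0.28 for inflammatory genes, and with the replicate block the adjusted p (limma camera) was 1.96e-05 and 0.000389. The limma camera adjusted p was 0.00142 for immediate-early and 0.0111 for inflammatory genes, and adjusted p = 0.85 for each with an estimated correlation; 0 members of either passed over all genes or over the list alone (limma; 3 and 5 at an unadjusted p under 0.05). Without miR-223 knockout replicate 1 both calls were lost (adjusted p 0.359 and 0.459), and without wild type replicate 2 the inflammatory call (0.551).

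**Figure D3:**
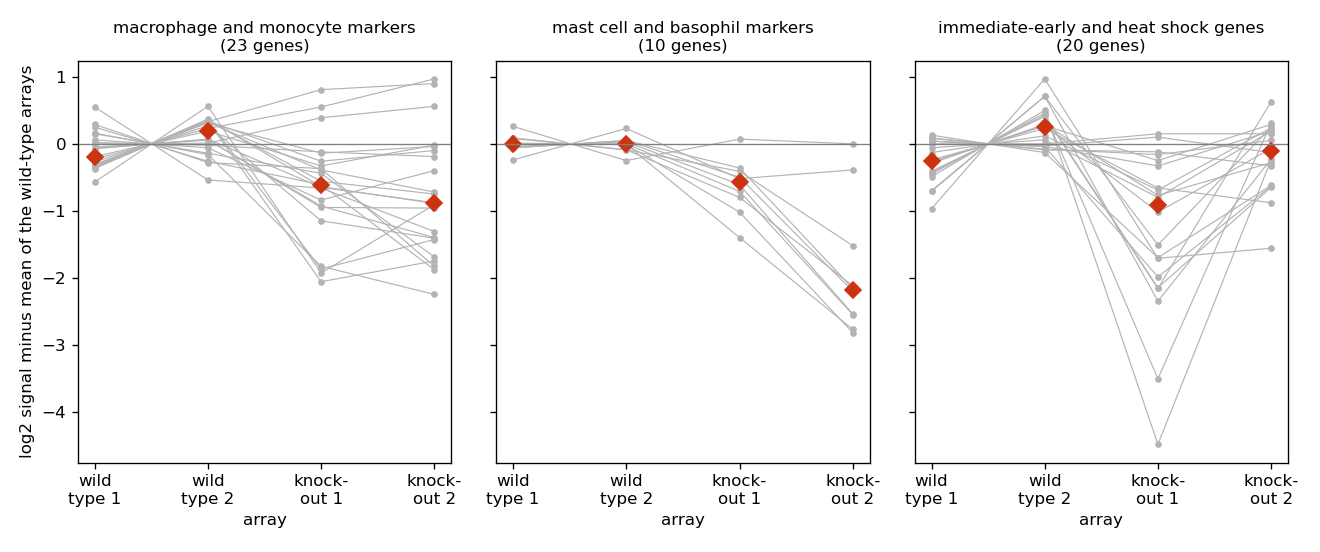
Log2 signal minus the mean of the wild-type arrays on each array (grey lines join the values of 1 gene, red diamonds mark the median) for macrophage and monocyte markers, mast cell and basophil markers, and immediate-early and heat shock genes. On knockout arrays 1 and 2 the medians are -0.61 and -0.89, -0.56 and -2.18, and -0.91 and -0.10.

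Cell cycle genes differed by small amounts. DNA replication genes fell by a median of -0.10, with 27 of 36 lower, including the origin-loading gene Cdc6 (-0.37 ± 0.12, another probe 0.07) and Rpa2 (-0.36 ± 0.13), while Rrm2, a subunit of ribonucleotide reductase, was at 0.69 ± 0.14. The list's median was -0.06 without wild type replicate 1 and -0.2 with spike-in scaling. The limma camera adjusted p was 0.0489, and adjusted p = 0.85 with an estimated correlation. The call was lost without wild type replicate 1 (0.275), without miR-223 knockout replicate 1 (0.102) or 2 (0.257) and under several settings, with adjusted p up to 0.531. Mitosis genes had a median of -0.02 over 39 members (limma camera adjusted p = 0.636; 0.0107 as lower without wild type replicate 2), with Nek2 at 0.59 ± 0.18 and the proliferation marker Mki67 at 0.19 ± 0.12. In both lists 0 members passed over all genes or over the list alone (limma; 3 and 1 at an unadjusted p under 0.05).

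Among 20 myeloid transcription factor genes the median was -0.05 (limma camera adjusted p = 0.332), from -0.14 with spike-in scaling to 0.05 without wild type replicate 1. Of these, 4 genes had an unadjusted p under 0.05, all lower, with 0 passing over all genes or over the list alone (limma). Irf8, required for monocyte development, was at -1.11 ± 0.25 and Klf4, which promotes monocyte differentiation, at -1.27 ± 0.37 (-0.79 without wild type replicate 2); macrophage and monocyte markers had a median of -0.76 on the same arrays. Cholesterol synthesis genes had a median of -0.05 and a mean of 0.01 over 24 members (limma camera adjusted p = 0.871), with Hmgcs1 at 0.64 ± 0.19. Interferon response genes had one of 0.00 over 24 (limma camera adjusted p = 0.973, ranked as lower), with Mx1 at -0.80 ± 0.12 and Ifit1 at 0.66 ± 0.12 passing adjusted over the list alone. Reference genes had a median of -0.03 over 12 members (0.659).

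Markers of other cell types gave no called list, though single members stood apart. The surface glycoprotein gene Thy1 was at 1.03 ± 0.13 (another probe 1.48) and the interleukin-7 receptor gene Il7r at -1.58 ± 0.20 (another probe -1.07), in a list of T and NK cell markers with a median of 0.03 and a mean of -0.38 over 9 members (limma camera adjusted p = 0.51, ranked as lower). Without wild type replicate 1 that median was -0.75. Among 15 stem and progenitor cell markers, with a median of -0.06 (0.692), the transcription factor genes Hlf and Meis1 were at 0.89 ± 0.14 and -0.97 ± 0.17 and Lmo2 at 0.91 ± 0.13. Siglecf, a lectin of eosinophils, was at 0.78 ± 0.12 and Alox15, a lipoxygenase gene, at -1.19 ± 0.27, and the 10 eosinophil markers had a median of -0.15 (0.692), which was -0.96 without wild type replicate 1 and 0.72 without wild type replicate 2. Car2, a carbonic anhydrase gene, was at 0.63 ± 0.13 among 8 erythroid markers with a median of 0.30 (0.51), and Itgb3 at 1.26 ± 0.14 among 10 megakaryocyte markers with a median of -0.45 (0.483), which was -0.15 without miR-223 knockout replicate 1 and -0.60 without miR-223 knockout replicate 2. Each of these 9 genes passed adjusted over its list alone, and 0 passed over all genes (limma). B cell markers had a median of -0.55 over 12 members, with 0 passing either way and 4 at an unadjusted p under 0.05, all lower, among them the signalling adaptor gene Blnk at -0.91 ± 0.32, or -0.47 without wild type replicate 2 (limma camera adjusted p = 0.193). The list's medians on the knockout arrays were 0.04 and -0.76 against the wild-type mean, and without miR-223 knockout replicate 2 the adjusted p was 0.699. That list passed as lower without wild type replicate 2 (0.0338), without miR-223 knockout replicate 1 (0.0246) and with the replicate block (0.047), and eosinophil markers passed as lower without wild type replicate 1 (0.00196) and as higher without wild type replicate 2 (0.0148).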

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

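The alternatives here were chosen before the data were examined, except the comparison with random lists matched on mean signal and the site counts in probe sequences, which were chosen after the results were seen. The signs of macrophage and monocyte markers (adjusted p from 2.24e-08 to 0.000527 without 1 array) and mast cell and basophil markers (4.58e-14 to 0.00745) and their calls held under every scaling, filter and camera fit with the preset correlation, and were lost with an estimated correlation (adjusted p 0.85) and with fry (0.365 and 0.616). With the estimated correlation all 10 called lists were lost at 0.85, in a test with few residual degrees of freedom that could hardly keep a call. For glycolysis and hypoxia genes the estimate was 0.0182, near the preset 0.01, yet the unadjusted camera p went from 0.00456 to 0.118. With fry the calls other than those of macrophage and mast cell markers were lost at 0.768 for dendritic cell and MHC class II markers, 0.673 for DNA replication, 0.365 for glycolysis and hypoxia, 0.825 for immediate-early and heat shock, 0.957 for inflammatory cytokine and NF-kB, 0.099 for miR-223 targets, and 0.551 for NADPH oxidase and for ribosomal protein genes. Fry does not compare a list with other genes. The count of genes past an adjusted p of 0.05, 0 by limma with 2275 at an unadjusted p under 0.05, was 4 with spike-in scaling (Btg4, Cfap206, Cst10, Olfr157), 5 with normexp and the 75th percentile (Mgam, Mt2, Orm1, Orm2, Serpinb10), 2 with array weights (Btg4, Cst10), 3 with all probes tested separately and 2 at an adjusted p of 0.1. It stayed 0 with the replicate block and without any 1 array, where the unadjusted count ran from 1078 (without miR-223 knockout replicate 2) to 2874. The knockout values of Btg4, Cst10, Cfap206 and Olfr157 lay at the floor of the signal. Gene calls with spike-in scaling, with array weights and at an adjusted p of 0.1 thus rest on a spread that is not that of the genes. Quantile normalization ended the calls of glycolysis (0.242), NADPH oxidase (0.242) and ribosomal genes (0.726), and normexp with quantile normalization the same calls (0.0671, 0.105, 0.553). NADPH oxidase genes also lost theirs with spike-in scaling (0.0784) and the replicate block (0.0505), and against matched random lists they (0.259) and ribosomal genes (0.391) did not stand apart, where mature neutrophil (0.00404) and specific granule genes (0.00468) stood higher and B cell (0.00223) and megakaryocyte markers (0.0039) lower. Matched random lists ignore correlation among the genes of a list. None of these lists had a call with the estimated correlation, a test that could hardly give one on 4 arrays. DNA replication genes lost theirs with median centring (0.0891), normexp and the 75th percentile (0.18), the authors' processed values (0.0969), no filter on dim probes (0.531), only probes well above background on all 4 arrays (0.0827) and the replicate block (0.0637). The replicate block also ended the call of miR-223 targets (0.0611) and gave one for B cell markers (0.047, lower). Without the filter, dendritic cell (0.0984) and inflammatory genes (0.101) lost their calls and specific granule genes gained one (0.0196), as with normexp and the 75th percentile (0.00393). The direction turned for lists that passed neither way: interferon response genes with spike-in scaling (0.925), normexp (0.947), quantile normalization (0.997), both (0.785), no filter (0.567), all 4 arrays above background (0.931), eBayes trend (0.962) and fry (0.957). It turned for X-chromosome neighbours of Mir223 with normexp (0.596), normexp and quantile (0.637), the replicate block (0.938), all 4 arrays (0.931), eBayes trend (0.847), fry (0.957) and matched lists (0.686). It turned for cholesterol genes with normexp (0.969), no filter (0.665) and fry (0.985), and for mitosis genes with normexp (0.969) and no filter (0.739). It also turned for stem and progenitor markers with normexp (0.969), normexp and quantile (0.785) and fry (0.978), azurophil granule genes with quantile (0.803), normexp and quantile (0.612) and matched lists (0.946). So did that of sex-linked genes with quantile (0.997), the replicate block (0.938), fry (0.985) and matched lists (0.751), reference genes with no filter (0.942) and eosinophil markers with fry (0.985). Leaving out 1 array, which leaves a group with 1 array assumed to vary like the others, gave adjusted p from 0.0319 to 0.122 for miR-223 targets, 0.000323 to 0.143 for ribosomal, 0.0165 to 0.123 for glycolysis, 0.0271 to 0.301 for NADPH oxidase and 0.0317 to 0.275 for DNA replication genes, 5.8e-05 to 0.285 for dendritic cell markers, 2.19e-13 to 0.359 for immediate-early and 8.62e-08 to 0.551 for inflammatory genes. Among the other lists it ran from 0.0246 to 0.699 for B cell and 0.00196 to 0.621 for eosinophil markers, 0.0317 to 0.718 for specific granule, 0.0107 to 0.504 for mature neutrophil and 0.0107 to 0.655 for mitosis genes. With a turned direction but no call it ran from 0.398 to 0.769 for azurophil granule, 0.0578 to 0.285 for cholesterol, 0.429 to 0.767 for interferon and 0.665 to 0.872 for sex-linked genes, 0.121 to 0.767 for stem and progenitor markers and 0.561 to 0.833 for the X-chromosome neighbours. Single genes turned sign: E2f1 (0 with spike-in scaling; -0.05 to 0.24 without 1 array), Eif2s3y (-0.02 with spike-in scaling; -0.04 to 0.19), Kdm5d (-0.02 with spike-in scaling; -0.11 to 0.26), Uty (-0.04 with normexp and the 75th percentile) and, without 1 array, Prg2 (-1.72 to 1.22), Prg3 (-2.23 to 1.19), Epx (-1.93 to 1.16), Ear1 (-0.74 to 0.65), Cd68 (-0.40 to 0.23) and Csf1r (-0.36 to 0.02). The correlation between replicates was 0.994 with normexp and quantile normalization, 0.983 without the filter and 0.990 to 0.994 without 1 array. Lists called with the replicate block numbered 8, against 10 without it. The labels do not say that equal replicate numbers belong together. Signal over background limited the genes tested, at 57.6% of probes on the dimmest array. The 1-slide hybridisation left no slide block to fit; the 3 alternatives for 3' UTR sites were not run. For the settings that ended a call, the cause was not tested.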

Other observations

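The 2 wild-type arrays differed in eosinophil granule genes by more than the genotypes did. Prg2, which encodes the major basic protein, stood at 2.17 on wild-type array 1 and 5.11 on array 2, against 3.16 and 3.63 in knockout. Prg3, Epx and Ear1 showed the same order of the wild-type arrays, at -1.96 and 1.46, 0.13 and 3.22, and 2.30 and 3.70. Over 9 eosinophil markers held by no other list the median gap between the wild-type arrays was 1.40, against 0.23 between the knockout arrays. The complement genes C1qa, C1qb and C1qc lay lowest on knockout array 2, at -2.77, -0.73 and -1.16, against -1.31, 0.52 and 0.11 on knockout array 1. These genes were chosen after their values were seen.

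Interferon response genes went both ways. Mx1, an antiviral GTPase gene, was at -0.80 ± 0.12, while Ifit1, Isg15 and Rtp4 were at 0.66 ± 0.12, 0.51 ± 0.14 and 0.75 ± 0.21 (n = 2 per group). In the megakaryocyte list the integrin gene Itga2b was at -1.64 ± 0.39 and the platelet receptor gene Treml1 at -0.59 ± 0.17. Gapdh, used as a reference gene and part of glycolysis, was at 0.26 ± 0.12. The probe of 49 genes was well above background on both wild-type arrays and neither knockout array, and that of 147 genes the reverse. Wild-type array 2 stood apart in this measure, with 57.6% of probes well above background against 62.2% to 63.5% on the others, and a lowest such signal of -5.39 against -6.30 to -6.60.

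All tests of explanations below were chosen, with their bounds, only after the results were seen, and the reading of the macrophage share test was revised after its value was seen. The mast cell and basophil markers fell by a median of -1.41, with knockout array 2 at -2.18 and array 1 at -0.56. If a smaller share of basophils or mast cells among the sorted cells were the source, their markers would fall by about the same amount. Over Mcpt8, Cpa3, Fcer1a, Ms4a2, Prss34 and Il4, held by no other list, the differences ran from -1.63 to -0.96. Their SD was 0.25, against a bound of 0.5 set for such markers. Over all 10 measured markers, 4 of them held by another list too, the SD was 0.65 and 1 marker was higher. On wild-type arrays Prss34 stood at 4.75 and 4.82 and Mcpt8 at 3.48 and 3.59, levels above the 75th percentile of the array. The labels do not give the sort gate, so whether such cells, or those of the macrophage lineage, could pass it is not known. If they could, their share may have differed between samples. With the gap of -1.75 between the knockout arrays, a difference by genotype and lower expression per cell, which was not tested, both stay open.

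The macrophage and monocyte markers fell on both knockout arrays, with medians of -0.61 and -0.89. Scale or brightness of the knockout arrays is argued against, since 0% of 10000 random lists matched on mean signal had a median as low. A smaller share of 1 macrophage-like population would lower its markers alike, but the differences of the 23 markers ran from -2.04 to 0.86, with an SD of 0.77, above the bound of 0.5. Since granulocytes may themselves express Csf1r, Cd68, Adgre1, Ctsl and Ly6c1, at levels not known here, a smaller share and a lower expression of part of the markers in the sorted cells cannot be told apart. These genes were named after their values, near 0 or higher, were seen. Under the rule used for mast cell and basophil markers, an SD of 0.77 would have counted against a smaller share. Irf8 (-1.11 ± 0.25) and Klf4 had the same sign but passed neither over all genes nor over the myeloid transcription factor list, where 8 of 20 members were higher and the median was -0.05 (limma camera adjusted p = 0.332; 0.05 without wild type replicate 1), and whether fewer monocyte-lineage cells or a changed fate of progenitors without miR-223 lies behind it was not tested.

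The immediate-early and heat shock genes lay at a median of -0.91 on knockout array 1 and -0.1 on knockout array 2, the latter within the bound of 0.3 set for a state of 1 culture or its handling. The wild-type arrays also differed, by a median of -0.50, and without miR-223 knockout replicate 1 the list's adjusted p (limma camera) was 0.359, in a range from 2.19e-13 to 0.85 over all alternatives. Replicate 1 lay below replicate 2 in both genotypes, and within the replicate numbers the medians were -0.74 and -0.29, with an adjusted p of 1.96e-05 with the replicate block (0.000389 for inflammatory cytokine and NF-kB genes). Over all tested genes, the differences of replicate 1 minus replicate 2 correlated at 0.17 between the genotypes, which gives little sign of pairing and does not decide it. Since the labels do not say whether equal numbers belong together, a state of 1 knockout culture and an effect of the genotype cannot be told apart, and the reading of this test was revised after these values were seen.

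A hypothesis is that loss of repression through miR-223 sites contributed to the differences. It was tested on the 60-base probes, which lie mostly near the ends of transcripts and cover little of the 3' UTRs: the 57 genes whose probe holds AACTGAC, the match to the miR-223 seed, had a mean moderated t 0.52 above that of the other genes and a median log2 difference 0.09 above. That excess ranked 5 among 322 heptamers of the same base composition with at least 20 genes (1.6%), and 6 by the median (1.9%). Several versions and other microRNA sites were looked at: the 8-base site gave 0.69 over 22 genes, the 6-base site 0.21 over 239, the reverse complement -0.07, and the sites of let-7 and of miR-15 and miR-16 gave 0.37 and 0.38, so that a positive excess is not special to miR-223. The other 8 microRNA sites looked at ran from -0.35 (miR-21) to 0.25 (miR-155), with -0.29 for miR-142-3p and -0.27 for miR-17, and the site of the miR-223 passenger strand gave 0.28. By the median, the let-7 site had an excess of 0.10, above that of the miR-223 site, the 8-base site 0.08 and the 6-base site 0. The rank was 3 to 7 under the scalings, 25 with no filter on dim probes and 14 with the replicate block. Without 1 array it was 33 (wild type replicate 1), 34 (wild type replicate 2), 15 (knockout replicate 1) and 6 (knockout replicate 2). With 1 wild-type array, or with no filter on dim probes, the site may thus not stand apart. Of random lists matched to the named targets, 0.36% had a median as high, but such lists ignore correlation among genes. With an estimated correlation the limma camera adjusted p of the named targets was 0.85, in a test with few residual degrees of freedom, and fry gave 0.099. Named targets may be among the 57 genes, which was not checked. The site and the named targets both have the sign that the hypothesis predicts, and they do not settle it.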
